A study of Mus musculus with 30 samples.

How the data were processed

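Liver mRNA of 30 libraries in 6 groups of 5 was read from 1 table of raw counts per gene. Per the labels, RNA was extracted with a column kit and made into strand-specific mRNA libraries from 1.5 µg of total RNA. Per the submitters' processing notes, reads were aligned with HISAT2 2.2.1 and counted with HTSeq 2.0.3 on build mm10. The deposited values are raw counts per gene, with no normalization by the authors. The annotation release, the strand setting of the counting and the mapping quality required are not given in the sources used here. The table held 48440 genes, of which 99.2% matched an identifier of GENCODE vM21, the source of coordinates, symbols and gene types. Its 5 summary lines of unassigned reads were left out of library sizes and tests. A median of 38.0% of the reads in the table were counted on genes, 43.4% lay on no gene and 11.0% aligned to more than 1 place. In 15 pairs of a noncoding gene overlapping a protein-coding gene on the opposite strand, the median ratio of reads per base, noncoding over coding, was 1.95. The ratio was over 0.5 in 13 of these pairs, so they do not bear out the strand-specific label. The cause was not tested, nor how many of the reads on no gene it concerns. Values of antisense and overlapping genes, like those of multigene families, are therefore uncertain.

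Groups came from each sample's treatment label. The labels name no batch and number the libraries from 1 to 30 without pairing them between groups. Replicates were compared before averaging, and the smallest chi-square per degree of freedom between 2 libraries of a group was 22.5. No library was thus a copy of another in its group, and libraries of different groups were not compared in this way. Counts were tested with edgeR 4.0.16 in R 4.3.3 (TMM normalization, filterByExpr, quasi-likelihood F test) in 1 fit of 30 libraries with 6 group coefficients and 24 residual degrees of freedom. That fit gives each gene 1 spread for all groups. The groups differed in spread: chi-square per degree of freedom between replicates was up to 269 in CDDP and up to 80.0 in PBS. Counts of changed genes therefore depend on which groups share a fit. The filter kept 16304 genes, and a gene was called changed at a Benjamini-Hochberg adjusted p under 0.05 within each of 10 comparisons. The 38 gene lists, 23 of pathways and 15 of cell markers or RNA quality, held 794 entries, 750 of them tested. They were fixed before the data were examined, as were the tests, the comparisons, the rule for naming genes and the alternatives except those said to be added. Lists were tested with camera of limma 3.58.1 at a correlation preset of 0.01, 2-sided and adjusted over the 38 lists, and again with an estimated correlation and with fry. List scores per library, the mean log2 CPM with a prior count of 2, were compared by 2-sided exact permutation tests, whose smallest p with 5 against 5 is 0.00794.

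Genes were named by this rule. Dbi was named in every comparison. Among changed genes with a mean of at least 5 CPM in 1 of the groups, a symbol that is not provisional and every library on its own side of the other group's mean, the 6 largest rises and 6 largest falls were taken; for interactions the condition on libraries was dropped. For each list with a camera adjusted p under 0.05 or at least 3 changed members, up to 3 changed members with the smallest p were taken. Where no gene passed, the 5 smallest p were taken, and members of a described list could be named. The text gives a part of these genes, selected with their values known. For overlaps of comparisons that share libraries, unchanged groups were simulated and the shared libraries were split 3 and 2.

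The test was tried on simulated counts, drawn with 1 spread per gene for all groups and so without the larger spread among CDDP libraries. With 225 of 16304 genes changed between CDDP and PBS it made 123 calls, 4 of them false, and recovered 12%, 32%, 80% and 92% of genes changed 1.5, 2, 4 and 8-fold. For the interaction it made 78 calls, 1 of them false, and recovered 2%, 8%, 52% and 88%. Alternatives were RLE normalization, no filter on low counts, a filter of 1 CPM in 5 libraries, a fold of at least 1.5 (glmTreat), DESeq2 1.42.0, limma voom with sample quality weights, a fit of only the groups compared, and leaving out each library in turn. Added after seeing the data were a muscle list score as a covariate and a fit without the 7 libraries richest in muscle or brain transcripts. These were 6 with a muscle score over 5, a limit chosen after seeing the scores, and ACBP replicate 4. Libraries that stayed in had muscle scores of up to 4.347 (CRS replicate 4), so muscle transcripts remained. Left were 4 PBS, 5 CDDP, 4 CRS, 3 ACBP, 4 CDDP+ACBP and 3 CRS+ACBP libraries. Python 3.11.15, pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9 were used for tables, permutations and figures.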

Results

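Liver mRNA was sequenced in 30 libraries from wild-type female C57BL/6J mice that were 8 weeks old when an osmotic pump was implanted. The pump held phosphate-buffered saline (PBS) or 2.5 mg/mL of ACBP, the acyl-CoA-binding protein that the gene Dbi encodes. Anorexia was induced 48 hours later by CRS, read here as restraint stress since the labels give the letters alone, or 72 hours later by CDDP (cisplatin), a drug that crosslinks DNA. The 6 groups of 5 libraries were PBS, CDDP, CRS, ACBP, CDDP+ACBP and CRS+ACBP, and the comparisons ask what each anorexia model and the ACBP pump changed in the liver. No group had food restricted alone. Effects of cisplatin or restraint therefore cannot be told apart from those of eating less, and a change after either is meant in that sense. Reads counted on genes ranged from 13957380 to 18479134 per library. In simulated data with 225 genes changed by cisplatin, 32% of those changed 2-fold and 80% of those changed 4-fold were recovered. Depth was that of these libraries, and each gene had 1 spread for all groups. The larger spread among CDDP libraries was not simulated, so recovery and false calls may differ in comparisons with CDDP. Recovery depends on how many genes change, and recovery with as many calls as in the data was not simulated. Levels are given as counts scaled to library size (CPM), mean ± SD over the 5 libraries of a group. Log2 fold changes are from edgeR's fit of all 30 libraries, on mouse build mm10, and are given ± an approximate SE. That SE is the absolute log2 fold change divided by the square root of the quasi-likelihood F. The labels do not state that each library came from a separate animal, so p-values rest on the spread between libraries. Dbi (ENSMUSG00000026385, chromosome 1, 120113280 to 120121078) stood at 614 ± 108 CPM in PBS and 636 ± 113 in ACBP. It did not pass the edgeR test in any of the 10 comparisons, with log2 fold changes from -0.15 to 0.39.

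**Figure D1:**
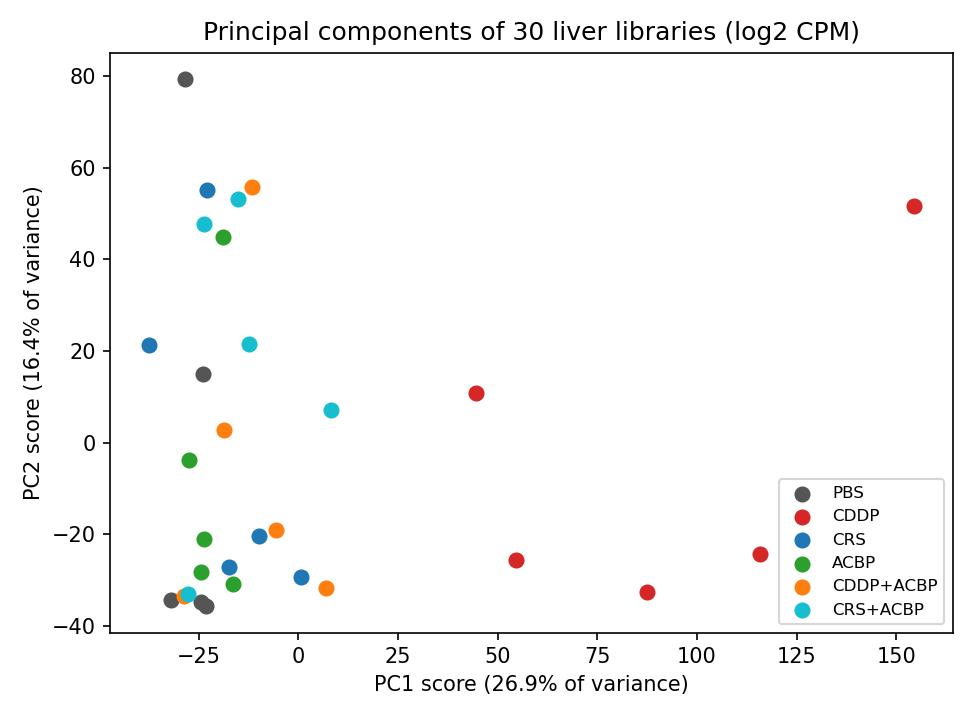
Scores of the 30 libraries on the first 2 principal components of log2 CPM, 1 point per library, coloured by group. The first component held 26.9% of the variance and the second 16.4%, and the 5 CDDP libraries lay between 44.6 and 154.5 on the first.

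Cisplatin was compared with PBS under the PBS pump. Targets of p53, the transcription factor of the DNA damage response, rose together. Cdkn1a, which encodes the cell cycle inhibitor p21 (ENSMUSG00000023067, chromosome 17, 29090976 to 29100727), rose from 3.23 ± 2.93 CPM in PBS to 311 ± 129 in CDDP (log2 fold change 6.58 ± 0.78). The exonuclease gene Aen rose from 11.7 ± 1.89 to 64.4 ± 14.6 CPM and Zmat3 from 3.57 ± 0.652 to 17.8 ± 6.07. Among p53 targets, 21 of 26 measured members rose and 0 fell (22 and 0 adjusted over the list alone). The p53 list had limma camera adjusted p = 1.81e-09 (up), and adjusted p = 0.0426 with an estimated correlation. Transcripts of acute phase proteins, which the liver secretes in inflammation, rose as well. Apcs rose from 78.6 ± 14.7 to 346 ± 57.1 CPM, and Serpina3n from 142 ± 16 to 1626 ± 1727, with 4673 CPM in CDDP replicate 5 and at most 1267 in the other CDDP libraries. Among acute phase genes, 24 of 27 measured members rose and 0 fell (25 and 0 adjusted over the list alone). The acute phase list had limma camera adjusted p = 3.02e-09 (up), and adjusted p = 0.39 with an estimated correlation. Globin transcripts of red blood cells fell, Hba-a1 from 223 ± 56.6 to 1.34 ± 0.353 CPM (log2 fold change -7.37 ± 0.63).

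In all, edgeR called 6756 of 16304 genes changed, 3771 higher and 2985 lower in CDDP. Against a fold of at least 1.5, 2646 passed. Glucocorticoid receptor targets included Sult1e1, an estrogen sulfotransferase gene, which rose from 0.591 ± 0.657 CPM in PBS to 137 ± 92.2 in CDDP. In this list 17 of 24 measured members rose and 1 fell (17 and 1 adjusted over the list alone), with limma camera adjusted p = 9.64e-05 (up), and adjusted p = 0.413 with an estimated correlation. The NRF2 target Srxn1, an antioxidant enzyme gene, rose from 22.2 ± 3.66 to 272 ± 235 CPM. Among NRF2 targets, 15 of 24 measured members rose and 0 fell (15 and 0 adjusted over the list alone). The NRF2 list had limma camera adjusted p = 3.34e-05 (up), and adjusted p = 0.39 with an estimated correlation. In the unfolded protein response, 15 of 22 measured members rose and 0 fell (16 and 0 adjusted over the list alone). That list had limma camera adjusted p = 3.34e-05 (up), and adjusted p = 0.483 with an estimated correlation. In the cholesterol synthesis list 14 of 25 measured members rose and 0 fell (15 and 0 adjusted over the list alone), with limma camera adjusted p = 0.000308 (up), and adjusted p = 0.505 with an estimated correlation. Igfbp1, which encodes a binding protein of insulin-like growth factors, rose from 74.6 ± 42.1 to 3539 ± 5486 CPM, with 13242 in CDDP replicate 5 and at most 2376 in the others. In the gluconeogenesis list, 11 of 17 measured members rose and 1 fell (12 and 1 adjusted over the list alone). Gluconeogenesis had limma camera adjusted p = 0.0175 (up), and adjusted p = 0.505 with an estimated correlation, and without CDDP replicate 5 the camera adjusted p was 0.175. In the autophagy and lysosome list, 20 of 33 measured members rose and 3 fell (20 and 3 adjusted over the list alone). It had limma camera adjusted p = 0.00625 (up), and adjusted p = 0.483 with an estimated correlation, and without CDDP replicate 5 the camera adjusted p was 0.0527. Asns, the asparagine synthetase gene, rose from 0.0743 ± 0.103 to 4.31 ± 3.05 CPM. Among ATF4 targets, 14 of 28 measured members rose and 2 fell (16 and 2 adjusted over the list alone). ATF4 targets had limma camera adjusted p = 0.0181 (up), and adjusted p = 0.39 with an estimated correlation, and without CDDP replicate 4 the camera adjusted p was 0.0613.

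Interferon-stimulated genes fell after cisplatin, Oas2 from 20.4 ± 4.32 CPM in PBS to 3.18 ± 0.895 in CDDP and Ifit3 from 18.8 ± 2.87 to 2.96 ± 1.34. In the interferon list, 3 of 34 measured members rose and 24 fell (3 and 24 adjusted over the list alone). Interferon genes had limma camera adjusted p = 1.1e-07 (down), and adjusted p = 0.39 with an estimated correlation. The sulfotransferase gene Sult2a8 fell from 268 ± 38.9 to 19.1 ± 6.78 CPM. In the list of xenobiotic cytochromes and conjugation, 6 of 31 measured members rose and 10 fell (8 and 11 adjusted over the list alone). It had limma camera adjusted p = 0.023 (down), and adjusted p = 0.505 with an estimated correlation, and without PBS replicate 3 the camera adjusted p was 0.0586. Mup3, a major urinary protein gene, fell from 1609 ± 380.1 to 36.9 ± 17.8 CPM. Among genes higher in male than in female liver, 5 of 24 measured members rose and 11 fell (5 and 11 adjusted over the list alone). The male-high list had limma camera adjusted p = 0.0465 (down), and adjusted p = 0.505 with an estimated correlation. Its camera adjusted p was 0.0606 with RLE normalization, and between 0.0504 and 0.0841 without any 1 of PBS replicates 2, 3 and 4, the 5 CDDP replicates, CRS replicate 4 and CDDP+ACBP replicates 1, 2 and 4. Reads of major urinary proteins, serum amyloids, alpha globins and serpins can be split among near-identical genes. In the list of PPARalpha and fatty acid oxidation, 9 of 36 measured members rose and 6 fell (9 and 6 adjusted over the list alone). Its median and mean log2 fold changes were 0.24 and 0.27, while camera put the list down (limma camera adjusted p = 0.567).

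Markers of cells other than hepatocytes also changed after cisplatin. Cd79a, part of the B cell receptor, fell from 2.22 ± 0.747 CPM in PBS to 0.253 ± 0.274 in CDDP. Among B and plasma cell markers, 0 of 12 measured members rose and 10 fell (0 and 11 adjusted over the list alone). These had limma camera adjusted p = 4.55e-06 (down), and adjusted p = 0.39 with an estimated correlation. Among T and NK cell markers, 0 of 14 measured members rose and 10 fell (0 and 11 adjusted over the list alone). Their list had limma camera adjusted p = 0.000292 (down), and adjusted p = 0.39 with an estimated correlation. Among erythroid markers, 0 of 8 measured members rose and 5 fell (0 and 6 adjusted over the list alone). The erythroid list had limma camera adjusted p = 0.00814 (down), and adjusted p = 0.483 with an estimated correlation. The Kupffer cell lectin gene Clec4f (ENSMUSG00000014542, chromosome 6, 83644542 to 83656187) fell from 137 ± 14.3 to 35.4 ± 18.9 CPM, and the scavenger receptor gene Marco rose from 8.3 ± 2.88 to 60.8 ± 36. Among Kupffer cell and macrophage markers, 1 of 15 measured members rose and 8 fell (1 and 8 adjusted over the list alone). The Kupffer list had limma camera adjusted p = 0.0038 (down), and adjusted p = 0.483 with an estimated correlation. Among stellate cell markers, 0 of 16 measured members rose and 7 fell (0 and 7 adjusted over the list alone). The stellate list had limma camera adjusted p = 0.0038 (down), and adjusted p = 0.505 with an estimated correlation. Its score did not pass the exact permutation test (CDDP minus PBS -1.06, p = 0.0873, adjusted p = 0.133). That score was 0.855 in CDDP replicate 5 and from 2.39 to 3.998 in the other CDDP libraries. For sinusoidal endothelium, 1 of 16 measured members rose and 8 fell (1 and 10 adjusted over the list alone). Endothelial markers had limma camera adjusted p = 0.0122 (down), and adjusted p = 0.505 with an estimated correlation. The endothelial score did not pass the exact permutation test (CDDP minus PBS -0.391, p = 0.119, adjusted p = 0.162). It was 3.055 in CDDP replicate 5 and from 3.964 to 4.525 in the other CDDP libraries. Among markers of pericentral hepatocytes, 1 of 18 measured members rose and 9 fell (2 and 9 adjusted over the list alone). The pericentral list had limma camera adjusted p = 0.0167 (down), and adjusted p = 0.413 with an estimated correlation. Chil3, a chitinase-like gene of myeloid cells, rose from 0.0985 ± 0.161 to 21.5 ± 16 CPM. In the neutrophil and inflammatory monocyte list, 4 of 8 measured members rose and 1 fell (4 and 1 adjusted over the list alone). That list did not pass (limma camera adjusted p = 0.27). Of mRNAs encoded in mitochondria, mt-Co1 fell from 34980.0 ± 4436 to 8419 ± 1633 CPM, and 0 of 12 measured members rose and 12 fell (0 and 12 adjusted over the list alone). The mitochondrial list had limma camera adjusted p = 1.37e-07 (down), and adjusted p = 0.39 with an estimated correlation. Mitochondrial transcripts took 3.44% ± 0.42 of the reads on genes in CDDP and 11.5% ± 1.85 in PBS (n = 5 each, 2-sided exact permutation p = 0.00794, the smallest the test can give).

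Restraint stress was compared with PBS under the PBS pump. Acute phase genes rose, among them Saa1 (ENSMUSG00000074115, chromosome 7, 46740497 to 46742980), a serum amyloid gene, from 10.9 ± 2.24 CPM in PBS to 1320.0 ± 570.1 in CRS (log2 fold change 6.92 ± 1.12). Lcn2, which encodes a protein that binds bacterial siderophores, rose from 10.2 ± 2.74 to 254 ± 97.5 CPM. Orm2 rose from 48.5 ± 17.2 to 432 ± 185 CPM, with 753 in CRS replicate 5 and at most 419.9 in the others. The organic anion transporter gene Slco1a1 (ENSMUSG00000041698, chromosome 6, 141907282 to 141946962), a male-high gene, rose from 11.8 ± 5.09 to 65.1 ± 33.4 CPM, and the receptor gene Tnfrsf14 from 0.447 ± 0.206 to 9.58 ± 1.54. Angptl8, which encodes a regulator of lipoprotein lipase, fell from 493 ± 319.8 to 83.8 ± 23.8 CPM, and the cytochrome gene Cyp2a22 from 473 ± 61.6 to 138 ± 62. In the acute phase list, 5 of 27 measured members rose and 0 fell (10 and 0 adjusted over the list alone). It had limma camera adjusted p = 3.26e-14 (up), and adjusted p = 0.417 with an estimated correlation. Among male-high genes, 1 of 24 measured members rose and 0 fell (14 and 0 adjusted over the list alone). That list had limma camera adjusted p = 3.39e-14 (up), and adjusted p = 0.0194 with an estimated correlation. No B and plasma cell marker passed on its own, and the list had limma camera adjusted p = 7.75e-05 (down), and adjusted p = 0.504 with an estimated correlation. None of 14 T and NK cell markers passed, and their list had limma camera adjusted p = 0.00583 (down), and adjusted p = 0.554 with an estimated correlation. None of 16 markers of sinusoidal endothelium passed, and these had limma camera adjusted p = 5.64e-06 (down), and adjusted p = 0.504 with an estimated correlation. Erythroid markers, 3 of 8 of which passed when adjusted over the list alone, had limma camera adjusted p = 0.000245 (up), and adjusted p = 0.504 with an estimated correlation. The score of a list is its mean log2 CPM in a library. In 7 lists the score passed the exact permutation test, with differences, CRS minus PBS, of 1.23 for acute phase, 1.15 for male-high genes, 0.507 for the unfolded protein response, -0.265 for iron handling, -0.361 for sinusoidal endothelium, -0.447 for T and NK cells and -0.669 for B and plasma cells (n = 5 each, 2-sided exact permutation p = 0.00794 and adjusted p = 0.0431 for each). With 5 against 5 or 4 against 5 libraries, at least 7 of the 38 lists must pass together for any to pass. No list score passed without any 1 of the 5 PBS replicates or CRS replicates 2, 3, 4 and 5. Without CRS replicate 1, 7 passed, and the B and plasma cell score was not among them (difference -0.677, adjusted p = 0.067). Over the fits without 1 PBS or CRS library the differences ranged from 1.16 to 1.28 for acute phase, 1.03 to 1.33 for male-high genes, 0.404 to 0.584 for the unfolded protein response, -0.301 to -0.244 for iron handling, -0.404 to -0.337 for sinusoidal endothelium, -0.494 to -0.368 for T and NK cells and -0.767 to -0.575 for B and plasma cells. Without the libraries richest in muscle or brain transcripts, 4 libraries stood against 4, where the smallest exact p is 0.0286 and at least 22 lists must pass together. The 7 lists all stood at that p, with differences, in the same order, of 1.25, 1.42, 0.607, -0.256, -0.389, -0.518 and -0.775.

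In this comparison edgeR called 23 genes changed, 19 higher and 4 lower in CRS. An unadjusted p under 0.05 was found in 1462 genes, 9% of those tested, where a share of 0.05 is expected if none changes. DESeq2 called 82, limma voom 930, a fit of PBS and CRS alone 265, and 5 passed against a fold of at least 1.5. The main fit also takes the spread of each gene from the CDDP libraries, which differed more among themselves than the PBS libraries. The count was 15 without PBS replicate 2 or CRS replicate 2, 9 without PBS replicate 5 or CRS replicate 3, 14 without CRS replicate 5 and 38 without CDDP replicate 5. It was 9 without the 7 libraries richest in muscle or brain transcripts, where muscle scores of up to 4.347 (CRS replicate 4) remained. Angptl8 missed the threshold without PBS replicate 4 or 5 or CRS replicate 3 or 5 (edgeR adjusted p from 0.0532 to 0.0807). Cyp2a22 missed it without PBS replicate 5 or CRS replicate 2, 3 or 5 (edgeR adjusted p from 0.0521 to 0.0807). Orm2 missed it without PBS replicate 2, 4 or 5 or CRS replicate 5 (edgeR adjusted p from 0.0529 to 0.0672), and Angptl8 and Orm2 without the libraries richest in muscle or brain transcripts (0.0902 and 0.0773).

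The ACBP pump was compared with the PBS pump in mice without an anorexia model. No gene passed the edgeR test, with 714 genes (4.4%) at an unadjusted p under 0.05, 9 called by DESeq2 and 2 by limma voom. The smallest p was that of Tnfrsf14, at 0.447 ± 0.206 CPM in PBS and 4.67 ± 3.49 in ACBP (edgeR adjusted p = 0.07). It passed without ACBP replicate 3 (edgeR adjusted p = 0.000494) and without CDDP replicate 4 (0.0303), and the count was 1 in each of these fits. No acute phase gene passed, and the list had limma camera adjusted p = 0.00018 (up), and adjusted p = 0.757 with an estimated correlation. The acute phase score was 8.048 in ACBP replicate 2 and from 7.348 to 7.534 in the other ACBP libraries. It did not pass the exact permutation test after adjustment (ACBP minus PBS 0.349, adjusted p = 0.151). Of the male-high genes none passed over all genes and 4 of 24 when adjusted over the list alone. The list had limma camera adjusted p = 0.00018 (up), and adjusted p = 0.757 with an estimated correlation.

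Within the restraint model, CRS+ACBP was compared with CRS, and Saa1 stood at 187 ± 189 CPM in CRS+ACBP beside 1320.0 ± 570.1 in CRS. No gene passed with edgeR, with 468 (2.9%) at an unadjusted p under 0.05. DESeq2 called 1, limma voom 3, and edgeR 1 without CDDP replicate 5. The CRS by ACBP interaction, the difference between the pump's effects with and without restraint, gave 0 genes with edgeR. In that interaction 388 genes (2.4%) had an unadjusted p under 0.05. DESeq2 called 4 there, limma voom 1, and edgeR 1 without CDDP replicate 5 or ACBP replicate 3. CRS+ACBP against ACBP gave 0 genes with edgeR, 1194 (7.3%) at an unadjusted p under 0.05, 20 with DESeq2 and 19 with limma voom. No male-high gene passed there over all genes and 12 of 24 rose when adjusted over the list alone. The male-high list had limma camera adjusted p = 3.12e-17 (up), and adjusted p = 0.00603 with an estimated correlation. Slco1a1 stood at 117 ± 37 CPM in CRS+ACBP (edgeR adjusted p = 0.236 against ACBP).

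Within the cisplatin model, CDDP+ACBP was compared with CDDP. Globin transcripts were higher in CDDP+ACBP, Hba-a1 at 423 ± 222 CPM beside 1.34 ± 0.353 in CDDP (log2 fold change 8.29 ± 0.65). Igfbp1 was lower, at 92.6 ± 56.7 CPM (log2 fold change -5.26 ± 0.81), and so was Cdkn1a, at 34.9 ± 24.3 CPM (log2 fold change -3.15 ± 0.66). Among p53 targets, 0 of 26 measured members rose and 11 fell (0 and 11 adjusted over the list alone). The p53 list had limma camera adjusted p = 0.000254 (down), and adjusted p = 0.364 with an estimated correlation. Among acute phase genes, 0 of 27 measured members rose and 22 fell (0 and 22 adjusted over the list alone). The acute phase list had limma camera adjusted p = 3.42e-09 (down), and adjusted p = 0.364 with an estimated correlation. In the interferon list, 21 of 34 measured members rose and 3 fell (24 and 4 adjusted over the list alone). Interferon genes had limma camera adjusted p = 6.82e-07 (up), and adjusted p = 0.364 with an estimated correlation. Among B and plasma cell markers, 11 of 12 measured members rose and 0 fell (11 and 0 adjusted over the list alone). These had limma camera adjusted p = 1.11e-07 (up), and adjusted p = 0.364 with an estimated correlation. Among erythroid markers, 6 of 8 measured members rose and 0 fell (6 and 0 adjusted over the list alone). The erythroid list had limma camera adjusted p = 8.14e-05 (up), and adjusted p = 0.364 with an estimated correlation. Of mRNAs encoded in mitochondria, 10 of 12 measured members rose and 0 fell (11 and 0 adjusted over the list alone). The mitochondrial list had limma camera adjusted p = 5.84e-06 (up), and adjusted p = 0.364 with an estimated correlation. Kupffer cell and macrophage markers did not pass as a list (limma camera adjusted p = 0.729), and 2 of 15 measured members rose and 3 fell (2 and 3 adjusted over the list alone). For PPARalpha and fatty acid oxidation the median and mean log2 fold changes were -0.10 and -0.21, while camera put the list up (limma camera adjusted p = 0.306).

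In this comparison edgeR called 5503 genes changed, 2432 higher and 3071 lower in CDDP+ACBP. The count was 2217 in a fit of CDDP and CDDP+ACBP alone, 3530 with limma voom and 1604 against a fold of at least 1.5. A fit of the compared groups alone takes the spread of each gene from them, the main fit from all groups. The CDDP by ACBP interaction, the difference between the pump's effects with and without cisplatin, was called in 3216 genes, 1367 positive and 1849 negative. Hba-a1 had an interaction of 7.46 ± 0.75 and Chil3 of -8.03 ± 1.41, the latter with edgeR adjusted p = 0.0503 without the libraries richest in muscle or brain transcripts. The interaction of Adcy1, -10.41 ± 1.76, was -5.15 without ACBP replicate 4, where Adcy1 stood at 56.8 CPM against at most 0.448 in the other ACBP libraries. The interaction count was 1722 without the libraries richest in muscle or brain transcripts and 825 against a fold of at least 1.5. Of the 6756 genes changed by cisplatin, 99.5% had the opposite sign in CDDP+ACBP against CDDP, beside 58.7% in simulated unchanged groups that shared the CDDP libraries. With the CDDP libraries split so that the fold changes shared none, the mean over 10 splits was 93.7% (87.8 to 98%, of 3210 to 5701 genes). For restraint the share was 73.9% of 23 genes, beside 78.1% in simulated unchanged groups, where a median of 463 genes was called. With the CRS libraries split, the mean was 53.4%, from 18.5 to 78.6% over 10 splits that called 14 to 577 genes.

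**Figure D2:**
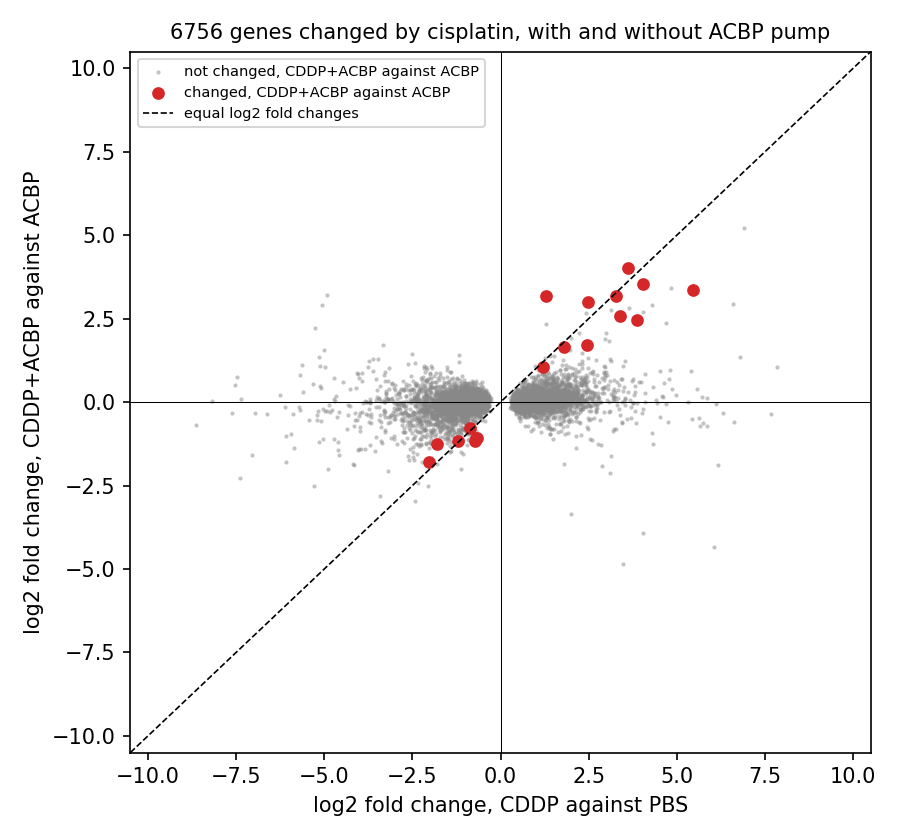
Log2 fold changes of the 6756 genes changed in CDDP against PBS (horizontal) and in CDDP+ACBP against ACBP (vertical), 1 point per gene, from comparisons that share no library. The 18 genes also changed in CDDP+ACBP against ACBP are in colour, and the median ratio of the vertical to the horizontal value was 0.048.

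Cisplatin under the ACBP pump was compared with the ACBP pump alone. Targets of p53 rose here too: Eda2r (ENSMUSG00000034457, chromosome X, 97333840 to 97377216), a receptor gene of the tumor necrosis factor family, from 0.233 ± 0.0962 CPM in ACBP to 2.8 ± 0.887 in CDDP+ACBP, and Aen from 9.77 ± 1.59 to 32 ± 20.1. Mdm2, which encodes the ubiquitin ligase of p53, rose from 35.5 ± 4.69 to 73.3 ± 38 CPM and the death receptor gene Tnfrsf10b from 0.469 ± 0.078 to 2.81 ± 1.57. Macrophage genes fell, Csf1r, the receptor gene for colony-stimulating factor 1, from 49 ± 3.92 to 28.7 ± 5.68 CPM. The complement gene C1qb fell from 36.9 ± 2.63 to 18.4 ± 3.98 CPM and the resident macrophage gene Timd4 from 6.84 ± 0.988 to 2.88 ± 0.765. Among p53 targets, 4 of 26 measured members rose and 0 fell (14 and 0 adjusted over the list alone). The p53 list had limma camera adjusted p = 2.45e-21 (up), and adjusted p = 0.00039 with an estimated correlation. Among Kupffer cell and macrophage markers, 0 of 15 measured members rose and 6 fell (0 and 12 adjusted over the list alone). The Kupffer list had limma camera adjusted p = 4.88e-28 (down), and adjusted p = 0.00039 with an estimated correlation. The p53 score was 4.33 ± 0.42 in CDDP+ACBP and 3.37 ± 0.09 in ACBP (n = 5 each). The Kupffer score was 3.64 ± 0.32 and 4.51 ± 0.13. Both had a 2-sided exact permutation p of 0.00794, the smallest possible, and an adjusted p of 0.101 over the lists.

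In this comparison edgeR called 21 genes changed, 11 higher and 10 lower in CDDP+ACBP. An unadjusted p under 0.05 was found in 790 genes, 4.8% of those tested and near the share expected if none changes. DESeq2 called 91, limma voom 70, a fit of ACBP and CDDP+ACBP alone 2, and 3 passed against a fold of at least 1.5. No gene passed with edgeR without the 7 libraries richest in muscle or brain transcripts, where the log2 fold change was 1.76 for Aen (adjusted p = 0.135) and 3.27 for Eda2r (adjusted p = 0.0768). The count was 39 without CDDP replicate 5 or CDDP+ACBP replicate 4, 5 without CDDP+ACBP replicate 1 or 3, 8 without ACBP replicate 2, 11 without ACBP replicate 3 or 4 and 12 without ACBP replicate 5. Csf1r missed the threshold without CDDP+ACBP replicate 1 (edgeR adjusted p = 0.0759), and C1qb without CDDP+ACBP replicate 1 (0.0761) or 3 (0.0634). Timd4 missed it without ACBP replicate 2 or 5 or CDDP+ACBP replicate 1 or 3 (edgeR adjusted p from 0.0692 to 0.098). Tnfrsf10b missed it without ACBP replicate 2 or 4 or CDDP+ACBP replicate 3 (edgeR adjusted p from 0.0565 to 0.0634). Mdm2 missed it without ACBP replicate 2, 3 or 4 or CDDP+ACBP replicate 1 or 3 (edgeR adjusted p from 0.0634 to 0.0793), and its log2 fold change went from 1.05 ± 0.20 to 0.68 without CDDP+ACBP replicate 3.

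**Figure D3:**
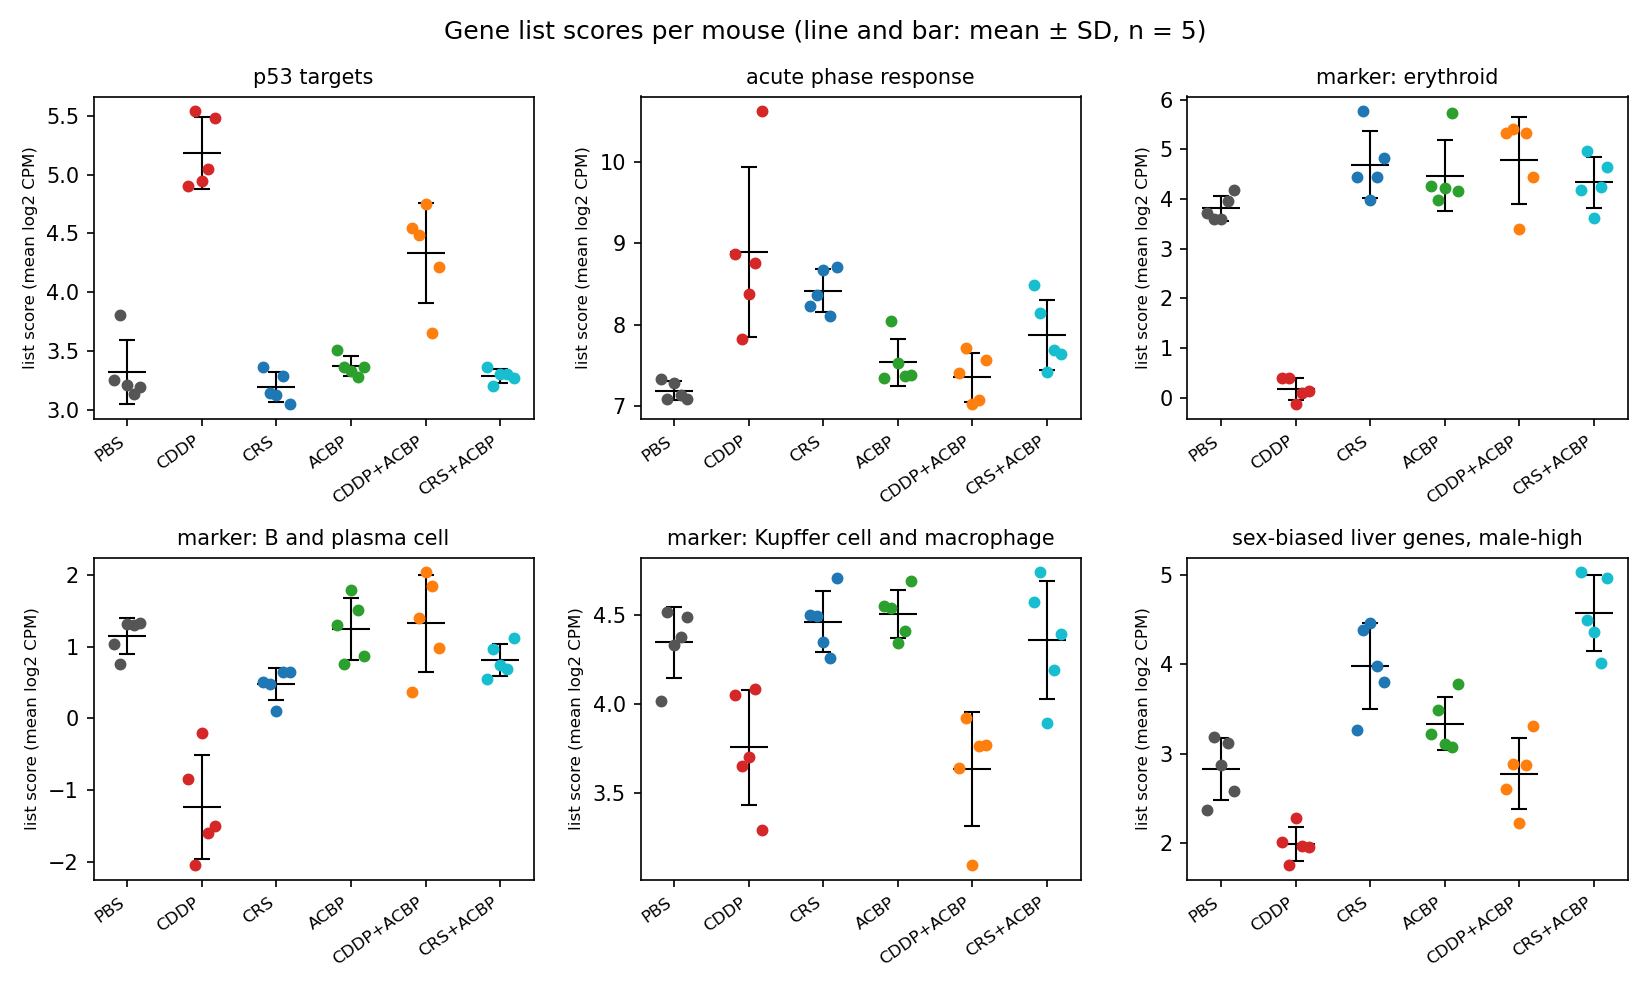
Scores of 6 gene lists (mean log2 CPM of the members) in the 6 groups, 1 point per library, with the group mean and SD (n = 5). The p53 score averaged 5.18 in CDDP, 4.33 in CDDP+ACBP and 3.37 in ACBP, and the Kupffer score 3.76, 3.64 and 4.51.

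The anorexia models were compared with each other under the PBS pump. Cdkn1a was higher in CDDP than in CRS (log2 fold change 7.68 ± 0.83), and the globin gene Hba-a2 (log2 fold change -8.92 ± 0.75) and Slco1a1 (-3.54 ± 0.44) were lower. Among p53 targets, 20 of 26 measured members rose and 0 fell (20 and 0 adjusted over the list alone). The p53 list had limma camera adjusted p = 1.04e-11 (up), and adjusted p = 0.0151 with an estimated correlation. Among male-high genes, 3 of 24 measured members rose and 17 fell (3 and 18 adjusted over the list alone). That list had limma camera adjusted p = 4.4e-07 (down), and adjusted p = 0.224 with an estimated correlation. Lists of RNA quality and of cell markers moved with them. For mRNAs encoded in mitochondria, 0 of 12 measured members rose and 11 fell (0 and 12 adjusted over the list alone), with limma camera adjusted p = 4.25e-07 (down), and adjusted p = 0.27 with an estimated correlation. For erythroid markers, 0 of 8 measured members rose and 6 fell (0 and 6 adjusted over the list alone), with limma camera adjusted p = 7.57e-05 (down), and adjusted p = 0.27 with an estimated correlation. For B and plasma cell markers, 0 of 12 measured members rose and 8 fell (0 and 11 adjusted over the list alone), with limma camera adjusted p = 0.000192 (down), and adjusted p = 0.27 with an estimated correlation. For T and NK cell markers, 0 of 14 measured members rose and 3 fell (0 and 1 adjusted over the list alone), with limma camera adjusted p = 0.00727 (down), and adjusted p = 0.39 with an estimated correlation. For Kupffer cell and macrophage markers, 1 of 15 measured members rose and 10 fell (1 and 11 adjusted over the list alone), with limma camera adjusted p = 0.000211 (down), and adjusted p = 0.27 with an estimated correlation. For pericentral hepatocyte markers, 2 of 18 measured members rose and 6 fell (2 and 6 adjusted over the list alone), with limma camera adjusted p = 0.00782 (down), and adjusted p = 0.27 with an estimated correlation. For PPARalpha and fatty acid oxidation the median and mean log2 fold changes were 0.32 and 0.40, while camera put the list down (limma camera adjusted p = 0.826). The edgeR count was 5639, 3177 higher and 2462 lower in CDDP, with 3709 in a fit of CDDP and CRS alone and 1790 against a fold of at least 1.5. Against PBS, 13 genes were higher in both models, 4 lower in both and 2 opposite. Both comparisons share the PBS libraries, and the overlap this sharing alone would give was not computed. Across genes, which are not independent replicates, the log2 fold changes of the models correlated at r = 0.363. In simulated unchanged groups that shared the PBS libraries r was 0.501, a value that the sharing alone sets. A response in 1 model alone widens its fold changes and lowers r, so the lower r does not show less overlap than the sharing gives. The covariance of the models' fold changes was 0.148, above the 0.0777 of those simulated groups. With the PBS libraries split, so that the fold changes shared none, the mean r was 0.157 and the mean covariance 0.0796.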

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

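The explanations weighed here were tested only after the results they concern were seen, while the splits of the libraries and the comparison of each library with its group were set before. In 152 sets of 5 values, 19 held a library far from the other 4 (a gap over 0.71 of the range). That limit is passed by chance in about 1 in 20 sets of independent, normally distributed values. Most sets here are CPM of genes selected with their values known, and the same libraries recur across sets. The 19 therefore cannot be read as an excess over chance.

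In CDDP replicate 5, Saa1 stood at 3732 CPM, Igfbp1 at 13242, Lcn2 at 1902, Serpina3n at 4673 and Adcy1 at 58.5, above the other CDDP libraries, and Oas2 at 1.61, below them. Dbp stood at 71.2 CPM in CDDP replicate 1. In ACBP replicate 4, Adcy1 stood at 56.8 CPM, Hba-a1 at 971 and the erythroid score at 5.73. Asns stood at 0.25 CPM in PBS replicate 5, Cyp2a22 at 243 in CRS replicate 1, Orm2 at 753 in CRS replicate 5, and Gria3 at 29.8 and Mdm2 at 139 in CDDP+ACBP replicate 3. The p53 score was 3.8 in PBS replicate 2 and the acute phase score 8.05 in ACBP replicate 2. CRS replicate 4 had 13957380 reads on genes, the fewest of all libraries, and 17.4% of them from mitochondrial genes.

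The effect of the ACBP pump differed between mice with and without cisplatin in 3216 genes, by the test of the interaction. Among reads the comparisons do not use, the share on no gene was 44.8% in CDDP and 43.3% in PBS. The share falling on more than 1 gene was 1.63% in ACBP, 1.91% in CDDP, 1.76% in CRS and 1.81% in CRS+ACBP, beside 1.51% in PBS. The share aligned to more than 1 place was lower, 6.715% in CDDP and 11.95% in PBS. Each of these 6 differences had a 2-sided exact permutation p of 0.00794 (n = 5 each) and an adjusted p of 0.0198.

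The CDDP+ACBP libraries lay close to the ACBP libraries while the CDDP libraries lay far from PBS. Mislabelling of the whole group is argued against by its p53 score, 0.963 above that of ACBP (2-sided exact permutation p = 0.00794, n = 5 each), and in its replicate 4 the p53 score, 3.653, lay above all libraries without cisplatin but PBS replicate 2 (3.804) and the Kupffer score, 3.766, under all of them (lowest 3.892), both on the side of its label, though 1 library excludes little. A response scaled down by 1 factor is argued against by the ratios of change with the ACBP pump to change without it: 0.517 for p53 targets (95% bootstrap interval 0.312 to 0.726) and -0.105 for the acute phase list (-0.355 to 0.0847). A lower exposure to cisplatin in CDDP+ACBP, with gene groups that differ in the exposure they need, cannot be told apart from an effect of ACBP on the response: the p53 score was 0.853 lower (-0.853) than in CDDP, and no drug level was measured. An effect of the ACBP pump, which the design names, stays open as a hypothesis. Whether a difference in food intake lay behind the pattern cannot be told, as no group had food restricted alone.

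Between CDDP+ACBP and ACBP 21 genes changed. RNA from muscle is argued against as the whole cause by the 21 of 21 genes that passed with the muscle score as a covariate. Brain RNA in ACBP replicate 4 is argued against by fold changes whose median ratio without and with that library was 1 (range 0.662 to 1.09), though 11 of the 21 genes passed without it. Without the 7 libraries richest in such transcripts, which leaves CDDP+ACBP replicate 3 with a muscle score of 3.973, no gene passed. The log2 fold change went from 1.71 to 1.76 for Aen and from -0.77 to -0.73 for Csf1r, so it stayed near its size in these genes. Whether the calls were lost to fewer libraries or to smaller changes was not tested for the 21 genes as a set. An effect of cisplatin that remained under the ACBP pump stays a hypothesis found and tested on the same libraries.

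Transcripts of red blood cells and of B, T and Kupffer cells were lower in CDDP than in PBS. The normalization, in which 1 factor per library moves all genes alike, is argued against by score changes that lay under that of the hepatocyte list, by -3.56 for erythroid (95% bootstrap interval -3.90 to -3.24), -2.31 for B and plasma cell (-2.90 to -1.66), -1.39 for T and NK cell (-2.14 to -0.722) and -0.508 for Kupffer markers (-0.954 to -0.0833). A lower share of all cells other than hepatocytes is argued against as the 1 cause of all these falls by unequal changes, -3.64 for the erythroid score (95% bootstrap interval -3.91 to -3.38) and -0.587 for the Kupffer score (-0.888 to -0.288). Without any 1 PBS or CDDP library, with genes filtered again, the erythroid change lay between -3.31 and -3.15, outside its interval. As a cause of the Kupffer change alone, a lower share of such cells was not tested. The endothelial and stellate scores changed by -0.391 and -1.06, and neither passed the exact permutation test (adjusted p = 0.162 and 0.133). Less blood in the tissue is argued against for Kupffer cells, which live in the liver, by that -0.587, but for transcripts of red blood cells, B cells and T cells it cannot be told apart from a loss of these cells: the neutrophil score was 1.38 higher in CDDP (2-sided exact permutation p = 0.00794, n = 5 each), yet it rests on 8 of 17 markers, which can also rise within cells. A loss of particular blood and immune cells after cisplatin was not tested, as cells were not counted.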

How the results depend on the processing

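Alternatives planned in advance were joined by 2 chosen after seeing the data, the muscle score as a covariate and the fit without the 7 libraries richest in muscle or brain transcripts (muscle scores of up to 4.347 remained), and by leaving out libraries in the opposition shares and both RLE and left-out libraries in the list scores. No paired analysis was possible because the labels share no numbers between groups. No named gene or list changed direction while called in any alternative. Named gene results that stayed on their side of the threshold, were lost and were gained numbered 453, 2 and 0 with RLE normalization, 446, 8 and 1 with no filter, 450, 2 and 0 with 1 CPM in 5 libraries, and 443, 1 and 10 with DESeq2. They were 372, 83 and 0 against a fold of at least 1.5, 405, 43 and 7 with limma voom, 405, 43 and 1 in fits of only the groups compared, 454, 0 and 1 with the muscle covariate, and 409, 46 and 0 without the libraries richest in muscle or brain transcripts. Over all fits without 1 library they were 13423, 222 and 5. Of 128 list calls, 122 were lost with an estimated correlation, 59 with fry, 19 without the libraries richest in muscle or brain transcripts, 3 with RLE and 0 with the muscle covariate; over all fits without 1 library, 129 of their values were lost and 3711 stayed. At this depth, with 225 genes changed, 12% of simulated 1.5-fold changes were recovered, and depth was not varied. The cause was not tested except where a stricter threshold explains a lower count.

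Comparisons are given in this order: CDDP, CRS and ACBP against PBS, CDDP+ACBP against CDDP, CRS+ACBP against CRS, the CDDP and CRS interactions with ACBP, CDDP against CRS, and CDDP+ACBP and CRS+ACBP against ACBP. Against a fold of at least 1.5 the gene counts moved to 2646 (CDDP against PBS), 5 (CRS against PBS), 1604 (CDDP+ACBP against CDDP), 825 (CDDP interaction), 1790 (CDDP against CRS) and 3 (CDDP+ACBP against ACBP). With limma voom they were 930 for CRS, 2 for ACBP, 3530 for CDDP+ACBP against CDDP, 3 for CRS+ACBP against CRS, 1 for the CRS interaction, and 70 and 19 against ACBP. With DESeq2 they were 82 for CRS, 9 for ACBP, 1 for CRS+ACBP against CRS, 4 for the CRS interaction, and 91 and 20 against ACBP. In fits of only the groups compared they were 265 for CRS, 2217 for CDDP+ACBP against CDDP, 1 for the CRS interaction, 3709 for CDDP against CRS and 2 for CDDP+ACBP against ACBP. ACBP against PBS gave 1 gene with no filter and 1 with the muscle covariate. Without the libraries richest in muscle or brain transcripts the counts were 9 for CRS and 1722 for the CDDP interaction. With edgeR the count there was 0 for CDDP+ACBP against ACBP. In all libraries that comparison had 790 genes (4.8%) at an unadjusted p under 0.05, and DESeq2 called 91 and limma voom 70.

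Leaving out 1 library at a time, the counts ranged from 5897 to 7073, 9 to 38, 0 to 1, 4581 to 6042, 0 to 1, 2495 to 3855, 0 to 1, 4711 to 6127, 5 to 39 and 0 to 0. Lists called ranged from 18 to 21, 8 to 12, 6 to 10, 14 to 22, 6 to 13, 14 to 20, 4 to 7, 16 to 19, 6 to 11 and 10 to 15, beside 20, 10, 8, 19, 8, 18, 6, 18, 8 and 13 with all libraries. With an estimated correlation limma camera called 1, 1, 0, 0, 0, 0, 0, 1, 2 and 1, and fry called 1 for CRS, 0 for ACBP, 0 for CRS+ACBP against CRS, 0 for the CRS interaction, 2 for CDDP+ACBP against ACBP and 1 for CRS+ACBP against ACBP. CRS+ACBP against CRS gave 13 lists without CRS replicate 1 or CRS+ACBP replicate 2 and 14 with the muscle covariate and the CRS interaction 2 without the libraries richest in muscle or brain transcripts. List scores that passed the exact permutation test ranged from 13 (without PBS replicate 5) to 21 for CDDP against PBS, 0 to 7 for CRS, 0 to 15 for CDDP+ACBP against CDDP and 7 to 19 for CDDP against CRS, beside 20, 7, 15 and 16 with all libraries, and from 0 to 0 in the other 4 comparisons. They were 0 for CRS without any PBS replicate or CRS replicate 2, 3, 4 or 5. For CDDP+ACBP against CDDP they were 0 without CDDP+ACBP replicate 2, 4 or 5, 7 without CDDP replicate 5 and 8 without CDDP+ACBP replicate 3, and for CDDP against CRS 7 without CRS replicate 2 or 5 and 8 without CRS replicate 4. In groups of 4 or 5 against 5, at least 7 of the 38 lists must pass together for any to pass. Without the libraries richest in muscle or brain transcripts they were 0 for CDDP+ACBP against CDDP, with 4 libraries against 5 and a p53 score difference of -0.89 beside -0.853 with all libraries. They were 0 for CRS too, with 4 libraries against 4, where the smallest exact p is 0.0286 and at least 22 lists must pass together, so that this 0 says nothing about these libraries. The acute phase score difference was 1.25 there, beside 1.23 with all libraries. The correlation of the CDDP and CRS responses ranged from 0.282 (without CRS replicate 3) to 0.419 and was 0.157 with the PBS libraries split. The share of opposite signs ranged from 99.1 to 99.6% for CDDP and from 60.9 to 85.7% for CRS. It averaged 93.7% (87.8 to 98%) and 53.4% (18.5 to 78.6%) over 10 splits of the model libraries. For CDDP it was 77.8% over the 18 genes also called under the ACBP pump.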

Other observations

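The splits of the libraries were set before their counts were seen, and the values of other tissues and lists below were looked at after seeing the data. In CRS+ACBP against ACBP, no heat shock gene passed over all genes and 4 of 19 rose when adjusted over the list alone. That list had limma camera adjusted p = 7.35e-08 (up), and adjusted p = 0.18 with an estimated correlation. In CRS+ACBP against CRS, no gene of PPARalpha and fatty acid oxidation passed over all genes. The list had limma camera adjusted p = 1.24e-05 (up), and adjusted p = 0.783 with an estimated correlation. In CDDP+ACBP against ACBP, no interferon gene passed over all genes and 2 of 34 fell when adjusted over the list alone. The interferon list had limma camera adjusted p = 1.97e-12 (down), and adjusted p = 0.239 with an estimated correlation.

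Muscle list scores ranged from -1.70 in CDDP replicate 2 to 7.12 in PBS replicate 2. In CDDP against PBS 2 of 12 muscle genes rose over all genes and 1 when adjusted over the list alone, while the median log2 fold change was -2.58 (limma camera adjusted p = 0.587, down). In CRS and ACBP against PBS the median was -1.29 and -2.03 while camera put the list up (limma camera adjusted p = 0.718 and 0.886). Of 12 brain markers, 9 were highest in ACBP replicate 4 of all libraries, Snap25 at 54.0 CPM (at most 1.36 in the other 29), Mbp at 64.6 (at most 3.07) and Mobp at 19.9 (at most 0.184). Slc1a2 and Syt1 were also seen in the other livers, with medians of 196 and 8.01 CPM.

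Libraries of the groups compared were split in 100 ways of the same sizes, the real split included. The real split gave the most genes for CDDP against PBS (6756 genes, highest other split 3301), CRS against PBS (23, highest other 0), CDDP+ACBP against CDDP (5503, highest other 3328), the CDDP by ACBP interaction (3216, highest other 2401), CDDP against CRS (5639, highest other 3396) and CDDP+ACBP against ACBP (21, highest other 1). In each of these only 1 split, the real one, gave as many genes. With 100 splits per comparison, chance is made less likely but is not excluded. For the interaction, labels were exchanged between CDDP and CDDP+ACBP and between PBS and ACBP. Those splits also remove any effect of the pump, so they do not test the interaction alone. The splits say nothing about chance where the real count was 0, which every split reaches: ACBP against PBS (0 genes, highest other 1), CRS+ACBP against CRS (0, highest other 0), the CRS by ACBP interaction (0, highest other 1) and CRS+ACBP against ACBP (0, highest other 0). There all 100 splits gave as many with edgeR. For these 4 the genes at an unadjusted p under 0.05 were 714, 468, 388 and 1194. They made up 4.4%, 2.9%, 2.4% and 7.3% of the genes tested, where a share of 0.05 is expected if none changes. Only the last lay above that share. DESeq2 called 9, 1, 4 and 20, and limma voom 2, 3, 1 and 19.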
